A study of Gallus gallus with 4 samples.

How the data were processed

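Breast muscle RNA of day 28 Isfahani and Ross 708 chickens was extracted with Trizol, per the labels' protocols. Equal amounts of RNA from 3 birds of a breed were pooled, and 2 pools per breed gave 4 libraries, made with a TruSeq version 2 kit and sequenced as paired-end reads of 150 bases on a HiSeq instrument, per the labels. The labels give no sex and no sequencing batch. Nothing in them says which birds entered which pool.

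Per the submitters' processing notes, the tools were FastQC 0.11.5, Trimmomatic, HISAT2 and Cufflinks 2.2.1, with the galGal5 build; the versions of Trimmomatic and HISAT2 and the gene annotation are not given in the sources used here. The expression table has the column layout of Cuffdiff, per the file headers. It holds 18973 rows, each with 1 FPKM value per breed as deposited, the log2 fold change of the deposited FPKM values, a test statistic (a score, per the file headers, not used here), and the authors' p-value and q-value. The library scaling and the dispersion model behind the FPKM are not given in the sources used here. The smallest deposited p-value is 5e-05, shared by 237 tested rows, which all have a q-value of 0.00245. The deposited q-values equal Benjamini-Hochberg values over the 11626 rows with status OK to within 5.22e-07. A further 7307 rows were not tested by the authors for low signal (NOTEST), 39 have status HIDATA and 1 has FAIL. Loci overlap where genes are close, and strand was not used as far as the sources used here state, so genes with an overlapping neighbour are less certain; 20 of the 105 genes named by rule overlap another row. Loci are given as deposited, and the convention for the first base is not stated in the file. The 3 enrichment sheets hold the authors' term counts, fold enrichment as a ratio, p-values and Benjamini-adjusted p-values, per the file headers; the tool is not given in the sources used here.

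Pooled breed values allowed no test per gene here. The design fixed before the data were examined had limma on log2(FPKM + 1) with camera and fry as its first option, and the authors' deposited q-values as its second in case the table held 1 value per breed; the second applied. A row was called when its deposited q-value was at or under 0.05. The reported ratio is log2((Ross 708 FPKM + 1)/(Isfahani FPKM + 1)), with a pseudocount of 1 FPKM. Depth could not be recovered: among 2680 untested rows above 0 in both breeds, the commonest 0.01-wide bin of log2 ratio held 0.709%, so no step of a single read was seen. Biological spread between birds is hidden in pools, and with 2 pools per breed the authors' test rests on little replication. The labels do not say that the pools came from separate flocks, so the p-values speak at most for these pools. How far they measure the spread between pools is unknown, since the dispersion model is not given.

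Gene lists (22, with 801 symbols) were written before the data were examined. They cover fast fibre, slow fibre, glycolysis, respiratory chain, mitochondrially encoded, fatty acid oxidation, lipid storage, extracellular matrix, myogenesis, IGF/PI3K/Akt/mTOR, TGF-beta/BMP/myostatin, proteolysis, ribosomal protein, creatine and amino acid, stress and immediate early, hypoxia, proliferation, leukocyte, endothelial, smooth muscle, nerve and erythroid genes. Of these symbols, 623 matched a row exactly. For a symbol on several tested rows the row with the highest mean FPKM was used, which gave 9202 genes as background, 499 of them called. In a first run 21 symbols absent from the table were also matched through RefSeq synonyms (GRCg7b, names alone). That matching was dropped after its results had been seen, because some synonyms joined a gene to a paralog (MYH3 to MYH1D, CASQ1 to CASQ2, ALAS2 to ALAS1), although others were true renamings (ATP5F1B to ATP5B). It had given 7 over-represented list directions, where exact matching gives 5 and leaves out the myogenic and the creatine and amino acid lists; its values are reported with the other alternatives.

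For each list, calls in each direction were compared with all other background genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over 42 list directions. A list's median ratio was placed among the medians of 10000 random lists matched in 20 bins of mean FPKM, as a description of these pools. Both steps were tested on simulated data with 9202 genes. Simulated lists of 30 genes shifted by 1, 2 or -1 log2 units were recovered by both; a shift of 0.5 reached percentile 100 without being called by Fisher's test. Of 100 unshifted lists, 4 lay outside the middle 95 percent and 0 were called. The simulated genes were independent and had the same spread, so these rates do not carry over to lists of genes that vary together.

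Genes were named by a rule fixed before the data were examined. It takes the 12 largest and 12 smallest ratios among calls with at least 5 FPKM in a breed and a single gene symbol, up to 4 called members per list with the smallest q-value, 18 growth-related genes whether called or not, and up to 6 genes per enrichment term described. Some genes the rule names are not reported here. Alternatives covered the threshold, a filter at 1 FPKM, recomputed q-values, unique symbols, a pseudocount of 0.1, centring on the median gene, and rescaling each breed to a common sum, which counts the HIDATA rows as deposited. After the data had been seen, 3 more were added: a sum without HIDATA rows, the row with the smallest q-value per symbol, and a background of at least 1 FPKM in both breeds. The synonym matching of the first run was kept as an alternative to the exact matching that replaced it. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.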

Results

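Messenger RNA was sequenced from the breast (pectoralis) muscle of 2 kinds of chicken at day 28 after hatching. Isfahani birds are native Iranian chickens, and Ross 708 is a commercial broiler line bred for fast growth and breast yield. Each breed was represented by 2 libraries, and each library was a pool of equal amounts of RNA from 3 birds, so 6 birds stood behind each breed. The values are the authors' FPKM, a unit of fragments per length of transcript and library size, with 1 value per breed and gene. The table calls the breeds "Native" and "Commercial"; the first matches the Isfahani label, and the second was taken as Ross 708 because no other group remained. No value per library was used here, so no breed value below has an SD or an n. The spread between pools could enter only through the authors' own test. Sequencing depth is unknown, because the values carry no trace of whole reads. The comparison asks how gene expression in growing breast muscle differs between a native breed and a broiler line, with the PI3K/Akt growth pathway named in the series title. Ratios are log2 of (Ross 708 FPKM + 1) over (Isfahani FPKM + 1), so positive values are higher in Ross 708, and they understate the change of low genes. Loci are on galGal5 with start and end as deposited.

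Calls higher in Ross 708 included 15 of 47 extracellular matrix genes, 10 of 24 lipid storage genes, 10 of 29 immediate early and heat shock genes and 5 of 16 slow and cardiac-type muscle genes. Calls higher in Isfahani included 5 of 34 genes of protein breakdown. Each of these 5 lists was over-represented (Fisher's exact test, two-sided, adjusted p from 6.96e-10 to 0.00499), but the protein breakdown list lost its call at a q-value threshold of 0.01 (adjusted p = 0.125) and with a log2 ratio of at least 1 (adjusted p = 0.189). Among calls with a single gene symbol and at least 5 FPKM in a breed, the largest ratio was that of PHGDH, the first enzyme of serine synthesis (chromosome 8, 4233644 to 4236981), at 0.336 FPKM in Isfahani and 23.4 in Ross 708, a log2 ratio of 4.19. ASNS, asparagine synthetase (chromosome 2, 24791279 to 24805274), stood at 4.93 and 54.1 FPKM, a log2 ratio of 3.22. Next to them were the retinol-binding gene RBP7 (3.73 and 69.3 FPKM), the lipid droplet coat gene PLIN1 (0.844 and 22.4 FPKM), the nuclear receptors NR4A3 (4.25 and 58.1 FPKM) and NR4A2 (2.39 and 23.6 FPKM), the lipogenic regulator THRSP (0.591 and 16.9 FPKM) and the secreted protein gene NELL2 (0.461 and 15.4 FPKM). The matrix protease gene MMP7 was listed at 0 in Isfahani and at 8.60 FPKM in Ross 708. The list was completed by TNC, ACTC1 and the row named RP5-966M1.6, which stood at 76.7 and 611 FPKM.

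In the other direction, TDH, a threonine dehydrogenase gene (chromosome 3, 106799832 to 106815181), stood at 133 FPKM in Isfahani and 10.1 in Ross 708, a log2 ratio of -3.59. CHAC1, which degrades glutathione (chromosome 5, 23730411 to 23732558), stood at 100.04 and 9.89 FPKM, a log2 ratio of -3.21. The chemokine gene CCL19 stood at 12.5 and 1.11 FPKM. PDK4, which restrains the entry of pyruvate into the citrate cycle, stood at 33.9 and 8.09 FPKM. ASB2, a subunit of a muscle ubiquitin ligase, stood at 180 and 49.5 FPKM, and KLHL38 at 6.43 and 0.857 FPKM. Other large ratios in this direction among calls with a gene symbol belonged to PM20D2 (95.5 and 24.1 FPKM), NT5DC1 (238 and 64.2 FPKM), GATSL2 (44.6 and 11.7 FPKM) and PGPEP1L (8.22 and 1.59 FPKM). KIFC1 (25.5 and 5.93 FPKM) and C8G (519 and 121 FPKM) are uncertain, because 7 and 2 other rows overlap their loci, as is PGPEP1L, which overlaps FAM169B. In the authors' deposited table the q-value was 0.00245, its smallest value, for each of these 24 genes except C8G (0.012) and THRSP (0.0106). NT5DC1 and GATSL2 also overlap another row and are less certain. The same holds for JUN, FADS2, PRDM4, COL18A1 and IRS2, among others named below.

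Of 11626 rows that the authors' deposited table marks as tested, 606 (5.21%) had a q-value at or under 0.05. Expression was higher in Ross 708 in 357 of them and higher in Isfahani in 249, so 58.9% of calls were higher in Ross 708. The median log2 ratio was 1.08 among the former and -1.03 among the latter, and 223 and 136 of them differed by at least 2-fold on this scale. The median of all 10020 tested rows with at least 1 FPKM in both breeds was -0.051. Calls named by a single gene symbol numbered 499. A further 65 calls had no gene name, 41 carried an Ensembl identifier or several names, and 1 was the less expressed row of its symbol. Some calls without a symbol differed as much as the named ones or more. Chosen after their values were seen, examples are XLOC_003479 (chromosome 11, 1768532 to 1768710), at 211 FPKM in Isfahani and listed at 0 in Ross 708, and ENSGALG00000013105, at 33.6 and 0.35 FPKM (log2 ratio -4.68). In the other direction, XLOC_009442 (chromosome 25, 743496 to 744607) stood at 26.2 and 451 FPKM, a log2 ratio of 4.05. Of all calls, 27 were listed at 0 in one breed, 10 in Isfahani and 17 in Ross 708, and have no fold. The counts fell by more than 1.5 times at a q-value threshold of 0.01, to 202 and 115.

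**Figure D1:**
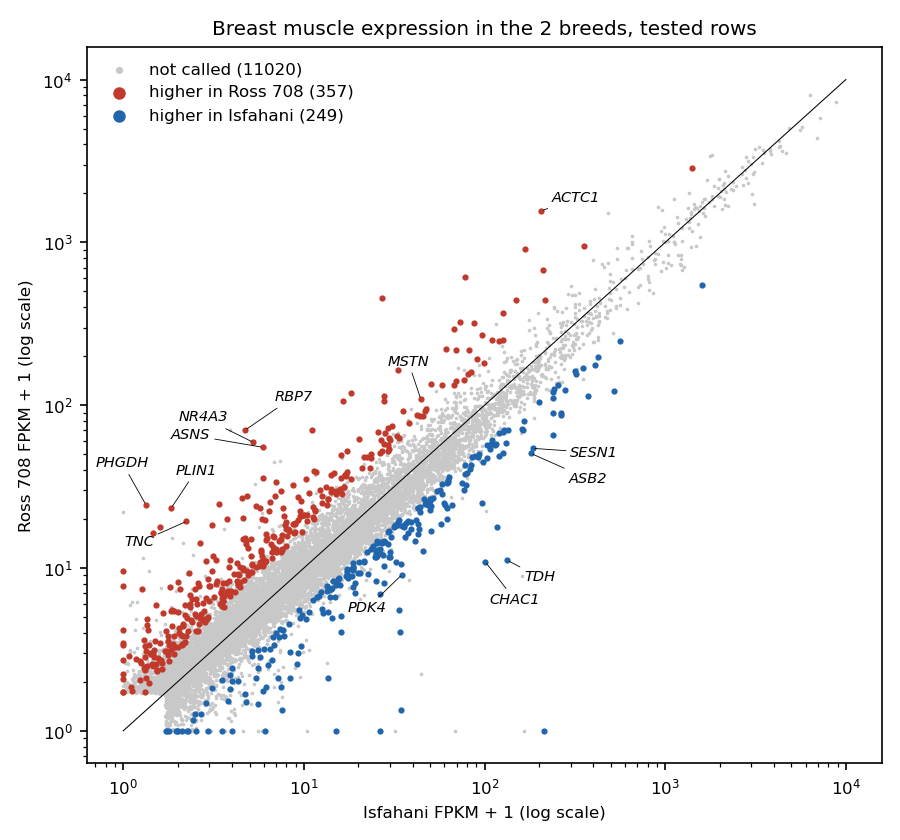
Breast muscle expression of each tested row in Isfahani (x axis, FPKM + 1, log scale) and Ross 708 (y axis, FPKM + 1, log scale), 1 value per breed with no error. Red points are the 357 calls higher in Ross 708, blue points the 249 calls higher in Isfahani, grey points the 11020 rows not called, and the line marks equal values.

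Many extracellular matrix genes were higher in Ross 708. Of 47 fibroblast and matrix genes tested, 15 rose and none fell, and 24 rose when p-values were adjusted over the list alone. TNC, the matrix protein tenascin C, stood at 1.24 FPKM in Isfahani and 18.3 in Ross 708, COL18A1 at 16.3 and 51.5, THBS1 (thrombospondin 1) at 8.33 and 26.5, and COL6A2 at 125 and 369. COL6A3 (49.4 and 133 FPKM) and fibronectin, FN1 (27.2 and 66.4 FPKM), were also called. The list's median log2 ratio was 0.79, at percentile 100 of 10000 random lists of the same size and expression. In the same pools the leukocyte list had a median of 0.56, the endothelial list 0.35, and the immediate early and heat shock list, a possible sign of handling, 0.61. Matrix genes were over-represented among calls higher in Ross 708 (Fisher's exact test, two-sided, 1.58 calls expected, adjusted p = 6.96e-10 over 42 list directions). Genes are not independent replicates, so this p describes the list in these pools.

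Of 24 adipocyte and lipid storage genes tested, 10 were called higher in Ross 708 and none lower, and 11 when adjusted over the list alone. Beside RBP7, PLIN1 and THRSP these included SCD, the desaturase that makes monounsaturated fatty acids (1.67 and 13.2 FPKM), LPL, lipoprotein lipase (6.03 and 32.7 FPKM), and FABP4, the adipocyte fatty acid carrier (86.7 and 320 FPKM). Members had a median log2 ratio of 0.66, at percentile 100 (Fisher's exact test, two-sided, adjusted p = 4.42e-08). On rescaling to the sum of all rows their median was 0.54. In the same pools the median log2 ratios of marker lists of other cell types were 0.56 for leukocytes, 0.37 for smooth muscle, 0.35 for endothelium and -0.18 for nerve, and in the main setting none of these 4 lists passed its test. The immediate early and heat shock list, a possible sign of handling, had a median of 0.61.

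The immediate early and heat shock list also held genes of the unfolded protein response. Of its 29 tested genes, 10 rose and none fell, and 14 rose when adjusted over the list alone. FOS stood at 66.6 and 294 FPKM, EGR1 at 32.3 and 162, ATF3 at 6.49 and 28.7, and JUN at 68.7 and 216. These transcription factor genes are known to respond quickly to many stimuli, handling and tissue collection among them. The median log2 ratio of all 29 tested genes of the list was 0.61, at percentile 100 (Fisher's exact test, two-sided, adjusted p = 2.59e-07). In the same pools the matrix, leukocyte and endothelial lists had medians of 0.79, 0.56 and 0.35.

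Of 16 genes of slow and cardiac-type muscle tested, 5 rose in Ross 708 and none fell; adjusted over the list alone, 7 rose and 2 fell. Cardiac actin, ACTC1 (chromosome 5, 31546120 to 31552902), stood at 206 and 1564 FPKM, cardiac troponin T, TNNT2, at 2.76 and 18.9, MYOZ2 at 5.09 and 18.6, and the slow calcium pump gene ATP2A2 at 4.81 and 11.5. ACTC1 shares long stretches of sequence with skeletal actin, ACTA1, which has no estimate in either breed, so its level is uncertain. This list of slow and cardiac-type genes had a median log2 ratio of 0.92, at percentile 100 (Fisher's exact test, two-sided, adjusted p = 0.00142). On rescaling to the sum of all rows the median was 0.78. Values were lower in Ross 708 for 5 of the 16 genes. The 2 that fell on adjustment over the list alone were MYBPC1 (9.87 and 6.07 FPKM) and MYH7B (2.92 and 0.663 FPKM). In the same pools the matrix, leukocyte, smooth muscle and endothelial lists had medians of 0.79, 0.56, 0.37 and 0.35, and the immediate early and heat shock list one of 0.61. Several of these muscle genes are expressed in developing and regenerating muscle as well as in slow fibres and heart. Of 13 fast fibre genes in the table, 5 were tested and 8 had no valid estimate. Of the 5 tested, 2 myosin heavy chain genes rose, MYH1D (10.3 and 38.4 FPKM) and MYH1A (80.04 and 154 FPKM), both also when adjusted over the list alone, and the list did not pass the test (adjusted p = 0.0631, median log2 ratio 0.34, percentile 97.1, and 0.21 on rescaling to the sum of all rows). Myosin heavy chain genes are a cluster of near copies, so reads can be shared among them.

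Some genes of protein breakdown were higher in Isfahani. Of 34 ubiquitin ligase, protease and autophagy genes tested, 5 were called higher in Isfahani and none in Ross 708, 29 were not called, and 6 were called when adjusted over the list alone. FBXO32, the atrophy-linked ubiquitin ligase atrogin-1 (chromosome 2, 137644049 to 137668779), stood at 25.4 and 11.4 FPKM, ULK1, a kinase that starts autophagy, at 12.9 and 5.63, the autophagy receptor gene SQSTM1 at 239 and 120.03, and the ubiquitin ligase gene FBXO30 at 29.5 and 14.5. TRIM63, the other classical atrophy ligase, stood at 217 and 125 FPKM and was not called (q = 0.0828 in the authors' deposited table). The list was over-represented among calls higher in Isfahani (Fisher's exact test, two-sided, adjusted p = 0.00499), but its median of -0.15 lay at percentile 28 of random lists and was -0.28 on rescaling to the sum of all rows and -0.099 on centring. In the same pools the immediate early and heat shock list, a possible sign of handling, had a median of 0.61. The matrix, leukocyte, smooth muscle and endothelial lists had 0.79, 0.56, 0.37 and 0.35. The list test was lost at a q-value threshold of 0.01 (adjusted p = 0.125) and when a log2 ratio of at least 1 was required (adjusted p = 0.189).

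Of 50 insulin, IGF, PI3K, Akt and mTOR signalling genes tested, 4 were higher in Isfahani, 2 were higher in Ross 708 and 44 were not called, where 1.03 and 1.68 calls were expected; adjusted over the list alone, 4 and 3 were. SESN1, a restrainer of mTORC1 (chromosome 3, 66543662 to 66556748), stood at 184 FPKM in Isfahani and 53.3 in Ross 708. The insulin receptor substrate gene IRS2 stood at 2.92 and 0.799 FPKM, and FOXO3, a transcription factor that Akt inhibits, at 24.03 and 11.6. SGK1, a kinase related to Akt, was higher in Ross 708 at 32.7 and 61.97 FPKM. The median log2 ratio was -0.12, at percentile 8.98, but -0.25 on rescaling to the sum of all rows and -0.072 on centring. The list was over-represented neither among calls higher in Isfahani (Fisher's exact test, two-sided, adjusted p = 0.0727) nor among those higher in Ross 708 (adjusted p = 1).

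Of the growth genes fixed for naming, those of this pathway other than FOXO3 were not called. IGF1 was on 2 tested rows at the same locus, at 18.1 and 14.1 FPKM and at 1.72 and 3.66 FPKM, with q-values of 0.966 and 0.459 in the authors' deposited table. IGF2 stood at 6.71 and 8.65 FPKM, IGF1R at 3.16 and 2.51, INSR at 4.84 and 3.61, and IRS1 at 15.2 and 9.67. PIK3R1 stood at 24.5 and 22.97 FPKM, AKT1 at 14.5 and 12.1, MTOR at 4.34 and 4.99, and FOXO1 at 4.31 and 4.33. In the authors' deposited table the q-values of IGF2, IGF1R, INSR, IRS1, PIK3R1, AKT1, MTOR and FOXO1 ran from 0.184 for IRS1 to 0.995 for FOXO1.

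Myostatin, MSTN, a secreted inhibitor of muscle growth (chromosome 7, 195584 to 202137), was higher in Ross 708, at 43.3 FPKM in Isfahani and 108 in Ross 708, a log2 ratio of 1.30 (q = 0.00245 in the authors' deposited table). Of 30 genes of TGF-beta, BMP and myostatin signalling, 4 were called higher in Ross 708 and 2 higher in Isfahani, and 7 and 4 when adjusted over the list alone. TGFB3 (89.8 and 190 FPKM) and BMP5 (2.46 and 5.99 FPKM) were among the former, and BMP7 (1.68 and 0.271 FPKM) among the latter. This list had a median log2 ratio of 0.18, at percentile 99.7 (0.091 on rescaling to the sum of all rows), and it did not pass the test (adjusted p = 0.0727 for genes higher in Ross 708).

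**Figure D2:**
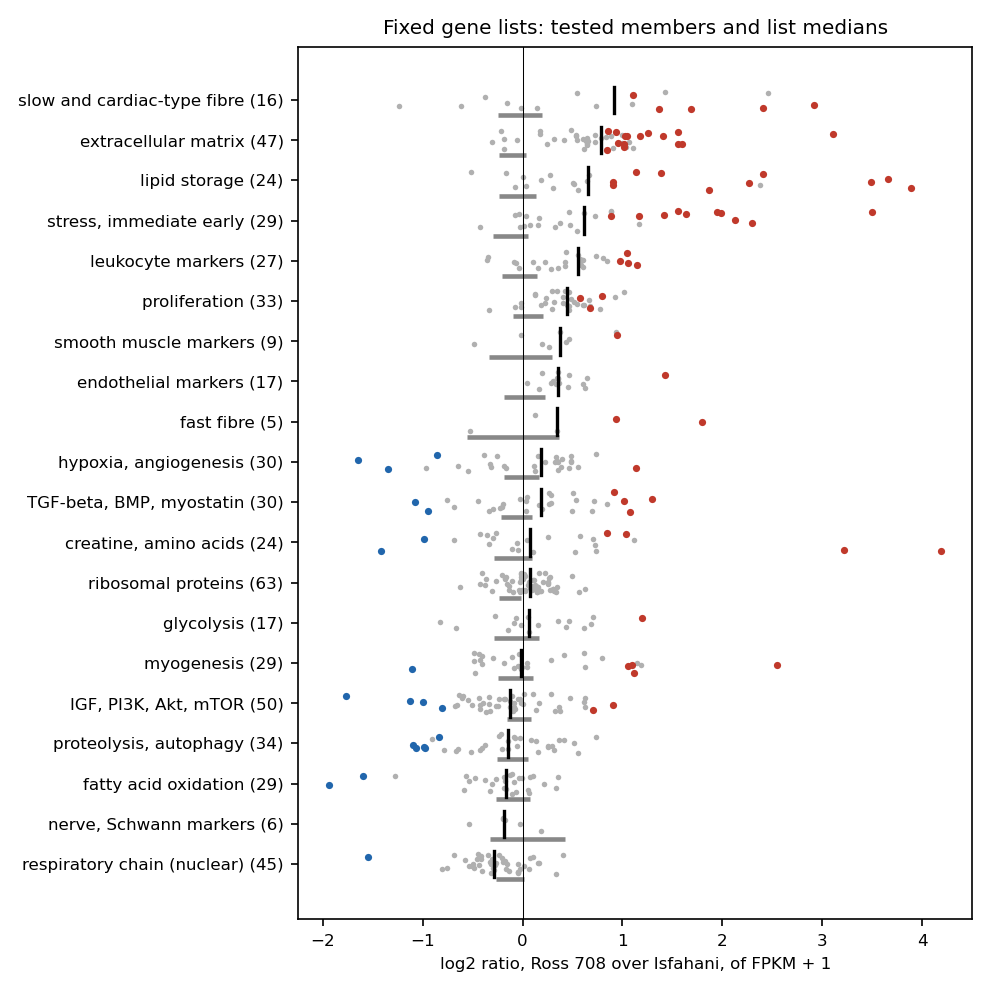
Log2 ratio of Ross 708 over Isfahani (x axis, of FPKM + 1) for the tested members of 20 gene lists (y axis, number tested in brackets). Each point is a gene, red if called higher in Ross 708, blue if called higher in Isfahani and grey if not called; black ticks are list medians, and the grey bar under each list spans percentiles 2.5 to 97.5 of the medians of random lists. Slow and cardiac-type muscle, matrix, lipid storage, and immediate early and heat shock genes have medians of 0.92, 0.79, 0.66 and 0.61, and respiratory chain genes the lowest, -0.29.

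Of 45 nuclear genes of the respiratory chain, 1 was called, UQCRQ (8.67 and 2.31 FPKM), higher in Isfahani, also when adjusted over the list alone. The median log2 ratio was -0.29, at percentile 1.02 of random lists whose own medians centred on -0.13, and the calls were not over-represented (adjusted p = 1). On rescaling to the sum of all rows the median was -0.42, and on centring -0.24. Of 29 fatty acid oxidation genes, 2 were called higher in Isfahani, PDK4 and the mitochondrial carrier gene UCP3 (263 and 86.2 FPKM), and the same number when adjusted over the list alone (adjusted p of the list = 0.33, median log2 ratio -0.17, percentile 22.6 of random lists whose own medians centred on -0.099). That median was -0.30 on rescaling to the sum of all rows. No mitochondrially encoded gene had a row of its own.

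Of 17 glycolysis genes tested, ALDOC (25.7 and 60.2 FPKM) was called, higher in Ross 708, and alone when adjusted over the list alone; 4 others had no valid estimate. The median log2 ratio of 0.062, at percentile 86.8, turned to -0.057 when values were rescaled to a common sum of all rows, and was 0.11 on centring and without the HIDATA rows in the sum, which are listed at 0 in Isfahani. The list did not pass the test (adjusted p = 0.864). Among 24 genes of creatine and amino acid metabolism, 4 rose in Ross 708 and 2 were higher in Isfahani, and 7 and 3 when adjusted over the list alone. Besides PHGDH and ASNS, the creatine synthesis gene GATM was higher in Ross 708 (37.1 and 77.1 FPKM), and ADSSL1, an enzyme of the purine nucleotide cycle, was higher in Isfahani (239 and 89.0 FPKM). This list missed the threshold (adjusted p = 0.0551) and passed it narrowly (adjusted p = 0.04995) when only symbols on a single row were used and with the synonym matching of the first run (adjusted p = 0.0473). Its median of 0.073, at percentile 96.1, turned to -0.036 on rescaling to the sum of all rows and was 0.13 without the HIDATA rows and 0.12 on centring. None of 63 ribosomal protein genes was called in the authors' deposited table, over all genes or adjusted over the list alone. Their median of 0.072, at percentile 99.9, turned to -0.061 on rescaling to the sum of all rows and was 0.12 without the HIDATA rows and on centring.

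Of 27 leukocyte genes 4 rose in Ross 708 (5 when adjusted over the list alone), among them ITGB2 (7.28 and 16.2 FPKM), CSF1R (19.99 and 40.4 FPKM), LY86 (13.3 and 28.8 FPKM) and CD83 (3.13 and 8.14 FPKM). The list missed the threshold at an adjusted p of 0.0631, with a median log2 ratio of 0.56 at percentile 100 (0.46 on rescaling to the sum of all rows). It passed at a q-value threshold of 0.01 (adjusted p = 0.0138) and against a background of genes with at least 1 FPKM in both breeds (adjusted p = 0.0403). All 17 endothelial genes had higher values in Ross 708, with a median of 0.35 at percentile 99.7, but 1 was called, APLNR (1.21 and 4.92 FPKM), as when adjusted over the list alone (adjusted p of the list = 0.864). Of 9 smooth muscle markers, ACTA2 was called (10.5 and 21.3 FPKM), as when adjusted over the list alone, with a list median of 0.37 at percentile 99.04 (adjusted p = 0.646). None of 6 nerve and Schwann cell genes was called on either adjustment in the authors' deposited table, with a median of -0.18 at percentile 12.8 (-0.32 on rescaling to the sum of all rows). Of the erythroid genes 2 were tested and neither was called on either adjustment.

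Of 33 proliferation genes tested, 3 rose in Ross 708, TOP2A (1.21 and 2.85 FPKM), MKI67 (1.18 and 2.47 FPKM) and CENPF (0.797 and 1.67 FPKM), and 7 when adjusted over the list alone. The median was 0.45 at percentile 100, and the list did not pass the test (adjusted p = 0.295). The myogenic genes went both ways. MYOD1, a regulator of muscle cell fate, was higher in Isfahani (238 and 110.4 FPKM), while LMOD2 (0.267 and 6.40 FPKM), the fetal acetylcholine receptor gene CHRNG (8.69 and 19.8 FPKM) and XIRP1 (13.1 and 28.2 FPKM) were higher in Ross 708. PAX7, the satellite cell marker, stood at 6.33 and 5.89 FPKM and was not called. Of 29 myogenic genes, 4 rose in Ross 708 and 1 was higher in Isfahani, and 8 and 1 when adjusted over the list alone. The list missed the threshold (adjusted p = 0.072), and passed it when a log2 ratio of at least 1 was required (adjusted p = 0.0248) and with the synonym matching of the first run (5 of 31, adjusted p = 0.0243). Its median of -0.016, at percentile 78.2, and its mean of 0.21 differed in sign, and the median turned to 0.034 on centring, to 0.019 on rescaling to a sum without the HIDATA rows, and moved to -0.13 on rescaling to the sum of all rows.

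Of 30 hypoxia and angiogenesis genes, 3 were higher in Isfahani, CA9 (61.2 and 18.9 FPKM), FGF1 (28.7 and 10.7 FPKM) and FGF18 (14.5 and 7.56 FPKM), and 1 was higher in Ross 708, PGF (8.47 and 19.8 FPKM), with the same counts when adjusted over the list alone. The list did not pass the test (adjusted p = 0.0807), and its median of 0.19, at percentile 98.8 (0.085 on rescaling to the sum of all rows), and its mean of -0.0061 differed in sign. PPARGC1A, a regulator of mitochondrial gene expression, stood at 0.837 and 0.415 FPKM and was not called.

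The authors' own enrichment sheets describe the same calls. In the sheets named for Ross, 269 called genes were matched in the biological process terms and 84 in the KEGG terms, and each of them was higher in Ross 708, although the sheets' names contain the word "Down". The sheet named for the native breed held 164 genes, each called higher in Isfahani. The terms described here were chosen after the sheets had been read. The sheets' background was 16787 genes for the biological process terms and 6910 for the KEGG terms, whose identifiers carry the human prefix hsa. It was not the 9202 tested genes, so their enrichment is not one over genes measured in this muscle, unlike the list tests above. In the authors' deposited table of terms higher in Ross 708, extracellular matrix organization held 41 genes (7.58-fold enrichment, adjusted p = 2.75e-20), with TNC, MMP7, CYR61 (26.6 and 112 FPKM), COMP (60.3 and 219 FPKM), SFRP2 (10.7 and 37.6 FPKM) and COL18A1 showing the largest ratios. Cell migration held 59 genes in the authors' deposited table (adjusted p = 4.35e-12), among them RET (0.361 and 3.47 FPKM) and CXCL14 (2.15 and 10.8 FPKM). The PPAR pathway held 8 genes there (adjusted p = 0.0117 in the authors' deposited table), among them FADS2 (13.7 and 37.4 FPKM) and PLTP (2.11 and 8.62 FPKM).

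PI3K-Akt signalling was among the KEGG terms higher in Ross 708, with 21 genes, 2.82-fold enrichment and an adjusted p of 0.00163 in the authors' deposited table. ECM-receptor interaction (17 genes, adjusted p = 5.56e-09) and focal adhesion (24 genes, adjusted p = 4.82e-09) ranked above it in the authors' deposited table; the last included MYL12A (80.7 and 216 FPKM). Of the 21 PI3K-Akt genes, 15 also stood in ECM-receptor interaction and 18 in at least one of those terms, and the members with the largest ratios were TNC, COMP, THBS1, COL6A2, COL6A3 and FN1. The 3 others were CSF1R, FGF16 and SGK1, named after their values had been seen. Of the 50 tested genes of the fixed signalling list, 2 were among the 21, SGK1 and PIK3R3, the latter named after its value had been seen.

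**Figure D3:**
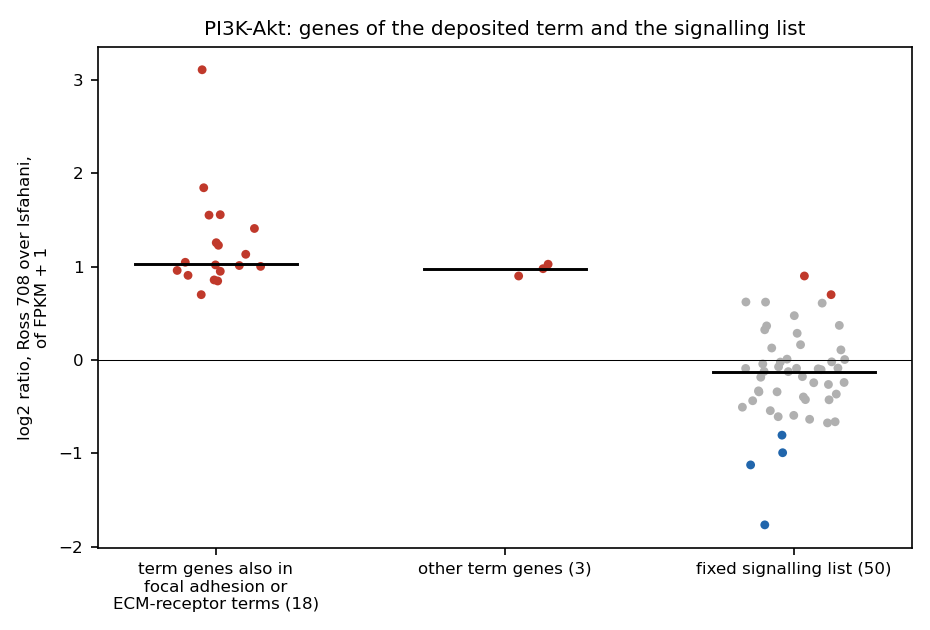
Log2 ratio of Ross 708 over Isfahani (y axis, of FPKM + 1) for the 18 genes of the deposited PI3K-Akt term shared with the focal adhesion or ECM-receptor terms, its 3 other genes, and the 50 tested genes of the fixed signalling list (x axis). Points are genes, red if called higher in Ross 708, blue if called higher in Isfahani and grey if not called, and black lines are medians; the signalling list has a median of -0.12. The first 2 groups hold called genes by construction.

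Among the terms higher in Isfahani, the lowest adjusted p-values in the authors' deposited table belonged to broad terms such as cellular protein modification process (67 genes, 0.00367) and macromolecule modification (69 genes, 0.00395). Cellular response to nutrient levels held 11 genes, with 6.39-fold enrichment and an adjusted p of 0.0096 in the authors' deposited table. Its members with the largest ratios were PDK4, MYOD1, the muscle cytokine gene IL15 (40.9 and 18.7 FPKM), ULK1, PRDM4 (34.9 and 16.7 FPKM) and glutamine synthetase, GLUL (47.4 and 23.4 FPKM). IL15 had another tested row at the same locus, at 1.59 and 1.02 FPKM and not called (q = 0.880 in the authors' deposited table). Response to starvation held 9 genes and missed the threshold (adjusted p = 0.0555 in the authors' deposited table); they included the glutamine transporter gene SLC38A3 (20.5 and 9.97 FPKM). Protein ubiquitination held 18 genes and missed it too (adjusted p = 0.209 in the authors' deposited table). Its largest ratios were those of KLHL38, ASB2, ASB11 (26.7 and 7.14 FPKM), WWP1 (125 and 49.7 FPKM), UBE2B (162 and 69.3 FPKM) and KLHL31 (421 and 196 FPKM).

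Some of the most abundant muscle genes could not be compared. The authors' deposited table gives 39 rows the status HIDATA, which in Cuffdiff marks loci with too many fragments to estimate, and all 39 are listed at 0 in Isfahani. In Ross 708, 8 of them are above 1000 FPKM, and together the 39 rows hold 11.9% of the breed's summed FPKM. Chosen after their values had been seen, examples are the fast troponin genes TNNI2, listed at 0 and 13272 FPKM, and TNNC2, listed at 0 and 11510.5 FPKM, and the lactate dehydrogenase gene LDHA, listed at 0 and 13191 FPKM. Of the 39 rows, 10 are listed at 0 in both breeds, among them skeletal actin (ACTA1), GAPDH and the fast light chain gene MYL1. None of these rows entered a test or a fold; their values entered only the alternative that rescales each breed to its full sum.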

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

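All tests in this part were chosen after the result was seen. One result drew attention as signal in rows that the comparison could not use: 8 rows with status HIDATA lie above 1000 FPKM in Ross 708 and are listed at 0 in Isfahani. They are TNNI2, LDHA, TNNT3, TNNC2, PGAM1, PKM, EEF1A2 and MYH1F, all abundant in fast muscle. Reading these zeros as absent transcripts is argued against by 10 HIDATA rows listed at 0 in both breeds, among them ACTA1, GAPDH and MYL1, which any skeletal muscle expresses. By its meaning in Cuffdiff the status itself marks loci that could not be estimated, though it does not say in which breed. The rows add nothing to this. At the 3 loci with several rows, 28 in all, 100% were HIDATA, but the status is given per locus, so that outcome decides nothing. Whether these genes also differ between the breeds stays open, since under this status the zeros listed for Isfahani cannot be taken as estimates.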

How the results depend on the processing

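Exact matching of list symbols, the main setting, replaced synonym matching after the list results of that first run had been seen. The smallest q-value row, the background of at least 1 FPKM in both breeds and the sum without HIDATA rows were also chosen after seeing the data. No paired analysis was possible because the table holds 1 value per breed; for the same reason leaving out each replicate, the replicate block, limma, camera and fry were not run. At a q-value threshold of 0.01 calls numbered 202 higher in Ross 708 and 115 higher in Isfahani (357 and 249 at 0.05), and 223 and 136 when a log2 ratio of at least 1 was also required; fewer genes pass by construction. The proteolysis list was then no longer over-represented (adjusted p = 0.125 and 0.189, 2 of 34 members called each time), while the matrix, lipid storage, immediate early and slow fibre lists passed under each alternative run. The share of calls higher in Ross 708 ran from 58.8% to 63.7%. Over-represented list directions numbered 5 in the main setting and 5 to 7 elsewhere. The 7 came from the synonym matching of the first run, which also held the myogenic list (5 of 31, adjusted p = 0.0243) and the creatine and amino acid list (4 of 24, adjusted p = 0.0473). Rescaling each breed to the sum of all rows moved the median gene by -0.13 (log2), and the ribosomal protein median turned from 0.072 to -0.061, with its percentile still 99.9. That sum counts the HIDATA rows, at 0 in Isfahani; without them the median gene moved by 0.041 and the ribosomal median was 0.12, so the turn came from those rows. Of 105 named genes, 19 missed the threshold of 0.01 and 13 the ratio of 1; the ratio of FOXO1, which was not called, turned from 0.0058 to -0.11 on rescaling to the sum of all rows and was 0.050 without the HIDATA rows. Unknown depth limits low genes most, and the pseudocount shrinks their ratios: with 0.1 FPKM the median ratio of calls higher in Ross 708 rose from 1.08 to 1.34.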

Other observations

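The tests in this part were chosen after the result was seen, except the list test of the signalling genes and the planned scalings. Sex was not given in the labels. Chickens of the female sex carry a Z and a W chromosome, males a pair of Z chromosomes, and Z-linked genes are only partly balanced between the sexes. The 518 Z-linked rows with at least 1 FPKM in both breeds had a median log2 ratio of -0.052 (quartiles -0.27 and 0.21), and the 9502 autosomal rows one of -0.051, whose chromosome medians ran from -0.11 to 0.04 over the 27 autosomes with at least 50 such rows. None of the 16 rows on W was tested by the authors, and the highest stood at 0.0222 FPKM in Isfahani and 0.12 FPKM in Ross 708.

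The matrix, lipid storage, leukocyte, endothelial and smooth muscle lists had medians above 0. A uniformly larger share of non-fibre cells was taken to raise them alike, but the 6 marker lists, nerve included, differed. The Kruskal-Wallis statistic over 130 genes had a permutation p of 9.0e-05, and of 0.0064 without the nerve list. This cannot decide on that explanation, because fibres express some members, the pseudocount shrinks low genes, and genes are not independent. Of the 10 pairs of the 5 lists with a median above 0, 1 differed, matrix and endothelial (0.79 and 0.35, permutation p = 0.0066 after adjustment over 15 pairs); the others had adjusted p from 0.0616 to 0.67. The scalings that were tried argue against library scaling by the size of their effect. The largest shift of the median gene over the scalings was 0.126, or 0.041 without the HIDATA rows in the sum. Both lie below the lower quartile of the matrix (0.53), endothelial (0.31), lipid storage (0.25), smooth muscle (0.20) and leukocyte (0.19) lists. The authors' own scaling is not given, so a larger error in it was not tested. A larger share of all non-fibre cells, higher expression per cell, a breed difference and a difference in dissection stay open. A rise of fibroblasts or adipocytes alone would not raise the endothelial and leukocyte lists, provided those cells do not express their members. All 17 endothelial genes had higher values in Ross 708 (percentile 99.7), as did 22 of 27 leukocyte genes, with 5 lower (percentile 100). Under that premise, which was not tested, these values argue against such a rise alone for both lists. Neither of the 2 lists passed Fisher's test in the main setting. For the matrix and lipid storage lists such a rise stays open. No gene stood on more than 1 of the 6 lists, but muscle fibres also express some of them, such as LPL; the most abundant members, chosen after their values were seen, were not called: CD74 (2138 and 2734 FPKM), COL3A1 (957 and 1582 FPKM), SPARC (991 and 1121 FPKM) and VIM (538 and 786 FPKM), and genes are not independent replicates.

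The deposited PI3K-Akt term may owe its place to matrix and integrin genes. Of its 21 genes, 18 also stand in the ECM-receptor or focal adhesion terms, and 15 in ECM-receptor itself, all of them matrix or integrin genes; the 3 others of the 18, PDGFRB, PGF and PIK3R3, are signalling genes. Higher RNA of the intracellular signalling genes as a set was not seen in the fixed list, where the adjusted p for genes higher in Ross 708 was 1 and the upper quartile of the log2 ratio was 0.084. That explanation cannot be told apart here, since members go both ways and a missed threshold shows no equality. Akt activity is set by phosphorylation, which RNA does not measure.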
